A study of Mus musculus with 8 samples.

How the data were processed

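RNA was measured in 8 libraries of mouse splenic B cells, sorted 7 days after immunization with the hapten NP on ovalbumin, given with LPS and alum. The labels describe the cells as NP-binding and tdTomato-positive, with a surface phenotype (B220+, CD138-, GL7-, FAS-, CD38+) that keeps memory B cells and leaves out germinal centre and plasma cells. The labels give AID-cre and the B1-8hi heavy chain for all libraries. A first group of 4 libraries was heterozygous for the targeted Zfp318 allele and the other 4 libraries were homozygous for it, named knockout here as in the labels. About 200 cells went into each library, and the protocol states that 5 mice were used in each experiment. Messenger RNA was copied with an oligo-dT primer and template switching, and the cDNA was amplified by 17 PCR cycles without molecular identifiers, so intervals from read counts cover counting error only. No label says that the libraries of a group came from separate mice, and p-values therefore measure only the spread between these samples.

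The submitters' processing notes name Trim Galore 0.6.6, STAR 2.2.0, featureCounts and the mm10 build, with no role or order. The deposited table holds a normalised signal per gene for each library, described by its name as normalised counts over coding sequence. The scaling method, the annotation and the strand setting are not given in the sources used here. In each library every deposited value was a whole multiple of the value of 1 read (100% of values within a tolerance of 0.05 reads), so reads could be recovered. Recovered totals were 10714819, 12451606, 15750240 and 13287011 reads in heterozygous libraries 1 to 4 and 8103572, 7995676, 9243162 and 14332493 in knockout libraries 1 to 4. Columns summed to between 1347284 and 1502273, and the value of 1 read implied a whole-number denominator of 5934661 to 10959324; what that denominator counts is not given in the sources used here. Of 22680 entries, 9059 were at 0 in every library, and 27 carried a spreadsheet date in place of a gene name, 2 of these names on 2 entries each; the genes behind them were not identified. Coordinates and coding lengths were taken from the GENCODE M21 annotation of the mm10 assembly, in which 20111 of the 22680 names matched 1 gene.

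Genes with a mean deposited value of at least 10 over the 8 libraries were tested (7996 genes). Knockout and heterozygous libraries were compared on log2(value + 1) with limma 3.58.1 (trended empirical Bayes, R 4.3.3), and p-values were adjusted by the Benjamini-Hochberg method, with genes called at an adjusted p under 0.05. Fold changes are knockout minus heterozygous on this scale, which understates the change of genes with low values. Lists of genes were fixed before the data were examined: 38 lists covering mitochondria, metabolism, stress, survival, B cell states, proliferation, immunoglobulin constant regions, neighbours of Zfp318 and other cell types. The 33 lists with at least 5 tested members were compared with all other genes by camera in limma, with a preset correlation between genes of 0.01 and a trended prior variance, and adjusted by the Benjamini-Hochberg method over those lists. Each list was also tested with an estimated correlation and with fry. Single measures were compared by exact two-sided permutation of the 8 libraries, for which the smallest possible p is 0.0286.

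The genes named in the text were chosen by a rule set before the data were examined: Zfp318, Ighm and Ighd; the 12 called genes with the smallest p in each direction among those whose groups did not overlap; up to 4 members with the smallest p in each called list and each mitochondria list; and up to 2 in the other lists. Gene models without a proper symbol, pseudogenes and receptor V, D and J segments were passed over and only counted (56 called genes). Genes outside the rule were chosen after their values were seen. Some genes that the rule names, and a test that used such a gene, are not reported here.

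The procedure was tested on simulated counts with the real means and depths, and with the same trended dispersions in both genotypes. The real spreads were unequal (median SD of log2 values 0.53 in the heterozygous and 0.20 in the knockout libraries), so the rates that follow may not hold for them. Among 7753 genes it recovered 34.4% of genes changed 2-fold and 73.3% of genes changed 4-fold; 3.88% of its calls were unchanged genes, and a draw without changes gave 0 calls. Alternatives fixed in advance were pseudocounts of 0.25 and 5, no filter or a mean of at least 50, TMM, quantile and column-total scaling, library weights, robust moderation, a replicate block, each library left out in turn, a threshold of 0.1, and the count models of edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads. Alternatives chosen after seeing the data averaged the knockout libraries to 1 sample, gave each genotype 1 weight, corrected for coding length and GC content, left out heterozygous libraries 1 and 3 together, and ran camera without the variance trend. Permutations, intervals and figures used Python 3.11.15 with scipy 1.17.1, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.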

Results

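The series examines memory B cell recall and the part that ZFP318 plays in it, with mitochondrial function named as its subject. The libraries analysed here allow 1 comparison, between NP-binding memory B cells heterozygous and homozygous for the targeted Zfp318 allele, with 4 libraries per genotype. Reads per library ranged from 7995676 to 15750240. Between 9890 and 10597 genes had a value above 0 in the heterozygous libraries and between 11438 and 11688 in the knockout libraries. Values are means ± SD of the deposited normalised values with n = 4 per genotype, fold changes are knockout minus heterozygous, and adjusted p-values are from limma with Benjamini-Hochberg adjustment unless another test is named.

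The targeted gene was measured first. Zfp318 (chromosome 17, 46383731 to 46420920, plus strand, mm10), which encodes a zinc finger protein needed for the long transcript that yields IgD, fell from 164 ± 26.4 to 2.53 ± 1.36, or 1.54% of the heterozygous level (log2 fold change -5.62, SE 0.36, adjusted p = 6.06e-06). Each knockout library lay at or below 3.71 and each heterozygous library between 139 and 194, so the values follow the labels in all 8 libraries. Ighd, the IgD constant region on chromosome 12, fell from 1457 ± 249 to 30.01 ± 6.68 (log2 fold change -5.57, SE 0.19, adjusted p = 2.58e-08). Ighm, the IgM constant region beside it, fell from 13990 ± 3897 to 3495 ± 261 (log2 fold change -1.97, SE 0.15, adjusted p = 1.76e-05). Ighm and Ighd are spliced from shared primary transcripts, and the falls went along with the difference in immunoglobulin makeup between the genotypes given next.

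**Figure D1:**
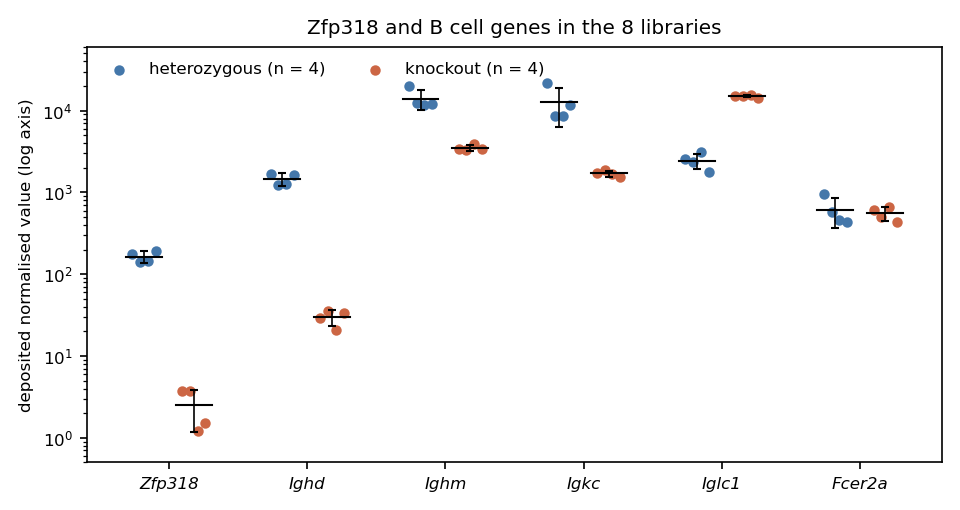
Deposited normalised values of 6 genes in 4 heterozygous and 4 knockout libraries, with 1 point per library. Zfp318 lies at or below 3.71 in the knockout libraries and between 139 and 194 in the heterozygous libraries.

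The genotypes also differed in the immunoglobulins that they expressed. The B1-8hi heavy chain is a rearranged gene built on Ighv1-72, and it binds NP when paired with a lambda-1 light chain; the labels give B1-8hi for both genotypes, and given the V reads that follow it is in doubt whether both groups carried it alike. Iglc1, the lambda-1 constant region, rose from 2451 ± 533 to 15113 ± 578 in the knockout (log2 fold change 2.65, SE 0.13, adjusted p = 7.42e-07), and lambda-1 made up 68.9% ± 1.48 of light-chain constant reads there against 13.4% ± 4.70 in the heterozygous libraries. Kappa made up 7.78% ± 0.455 of light-chain constant reads in the knockout and 62.7% ± 9.54 in the heterozygous libraries. Ighv1-72 supplied 86.7% ± 1.02 of heavy-chain V reads in the knockout and 8.96% ± 2.40 in the heterozygous libraries. Its own value rose less, from 162 ± 24.5 to 340 ± 67.0 in the knockout (log2 fold change 1.06, adjusted p = 0.00157). Summed heavy-chain V values were 1388 to 2894 in the heterozygous and 317 to 472 in the knockout libraries. The share of Ighv1-72 thus also grew because other V segments fell. Switched isotypes made up 50.3% ± 1.57 of heavy-chain constant reads in the knockout and 6.23% ± 1.76 in the heterozygous libraries, and Ighg2b rose by 2.25 on the log2 scale (adjusted p = 0.000341). Of 7 such measures, 6 separated the genotypes completely by exact two-sided permutation tests (p = 0.0286, the smallest possible; Benjamini-Hochberg adjusted p = 0.0333), and the share of Igkv14-126 among kappa V reads did not (exact permutation p = 0.2). Ighg2b and the V segments lie outside the rule for named genes and were chosen after their values were seen. Near-identical V and lambda constant segments can share reads, and reads of a mutated knock-in V gene can be lost in alignment to the reference. Iglc2 (2476 ± 481 in the heterozygous and 3116 ± 249 in the knockout libraries, adjusted p = 0.0819) and Iglc3 (2002 ± 262 and 1984 ± 114, adjusted p = 0.979) were not called. The V segment Iglv1 rose from 1996 ± 633 to 13070 ± 456 (adjusted p = 1.94e-05). These 3 were named after their values were seen.

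**Figure D2:**
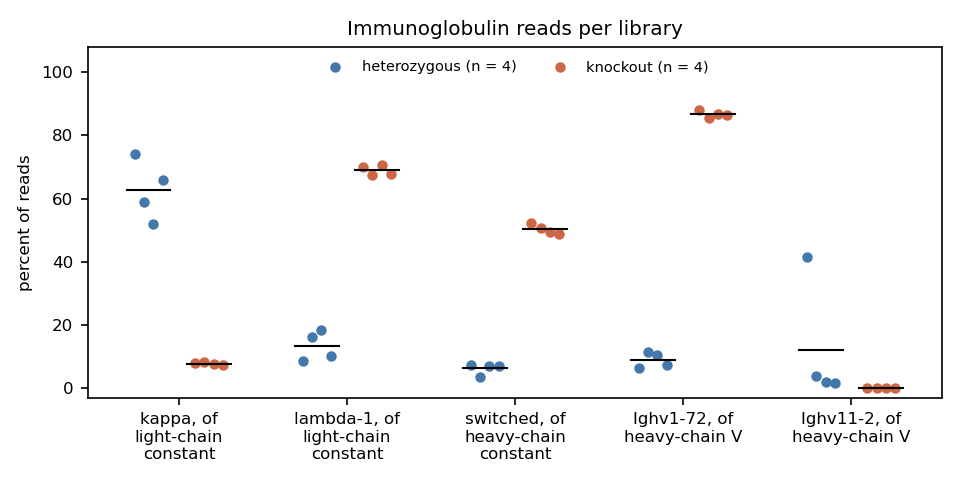
Percent of reads in each library for immunoglobulin measures, with 1 point per library and 4 libraries per genotype. Ighv1-72 supplies between 85.5% and 88.0% of heavy-chain V reads in the knockout libraries and between 6.51% and 11.5% in the heterozygous libraries.

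Across the transcriptome more genes fell than rose with the authors' scaling. In the knockout 271 genes rose and 1304 fell among 7996 tested, and 80 and 815 of these changed at least 2-fold. The groups did not overlap in 25.8% of genes, against 2.86% by chance. The split between directions rests on the scaling: under TMM scaling, which moved the median log2 fold change by 0.33, 613 genes rose and 616 fell, and edgeR and DESeq2 on recovered reads gave 486 and 646 higher and 727 and 952 lower. With the authors' scaling the median gene lay at -0.25. Genes higher in the knockout included H2-T23, a non-classical MHC class I gene (log2 fold change 1.12), Gimap7, a lymphocyte GTPase (1.65), Pglyrp1, a peptidoglycan recognition protein (1.47), and Serinc3 (1.21). Cd52 (0.69), Sh3bgrl3 (0.78) and Rpl37a (0.80) also rose. Jchain, the joining chain of secreted IgM and IgA, fell from 220 ± 81.6 to 8.04 ± 1.40, and Sf3a2, a subunit of the splicing factor SF3A, fell from 149 ± 11.96 to 7.40 ± 3.79. Ybx1, a nucleic acid binding protein, fell from 1735 ± 334 to 399 ± 36.8, and Hmces (-2.81), Gnas (-2.34) and Psip1 (-2.16) fell as well. Knockout libraries resembled one another far more than heterozygous libraries did (r from 0.974 to 0.978 against 0.777 to 0.807, and 0.795 to 0.832 between genotypes). Taking them as 1 sample left 4 higher and 42 lower genes; that comparison has fewer samples and only the spread of the heterozygous libraries, so it loses calls by construction. The gene groups that follow are compared between libraries that also differ in light chain (kappa 7.78% against 62.7%) and in Trac reads (2 against 15350).

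In the list of memory B cell markers more genes rose than fell in the knockout. Of 20 tested markers, 6 rose, 1 fell and 13 were not called, with 6 and 1 when adjusted over the list alone. Ccr6, a chemokine receptor carried by memory B cells, rose from 264 ± 36.8 to 1057 ± 23.4 (log2 fold change 2.01, SE 0.12, adjusted p = 2.98e-06). Gpr183, an oxysterol receptor that guides B cells in the follicle, rose from 198 ± 42.8 to 583 ± 22.3, and Cxcr3, a chemokine receptor induced by T-bet, rose from 72.9 ± 41.6 to 697 ± 48.4. Klf2, a transcription factor that controls lymphocyte trafficking, fell from 647 ± 163 to 192 ± 17.7. Camera called the list (adjusted p = 7.22e-05; adjusted p = 0.378 with an estimated correlation). Ccr6, Gpr183 and Cxcr3 also led the migration and adhesion list, in which 4 of 22 genes rose and 1 fell, as they did adjusted over the list alone; the member that fell was S1pr2, a receptor that holds cells in germinal centres (from 104 ± 34.8 to 10.5 ± 5.71). Camera called that list (adjusted p = 0.00869; adjusted p = 0.407 with an estimated correlation), with a median log2 fold change of -0.01 and a mean of 0.15.

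More germinal centre genes fell than rose. Of 20 tested, 14 fell, 6 were not called and 0 rose; adjusted over the list alone, 15 fell and 1 rose. Mef2b, a transcription factor that drives Bcl6, fell from 297 ± 60.7 to 43.98 ± 11.9, and Bcl6, the master regulator of germinal centre B cells, fell from 320 ± 67.04 to 74.6 ± 13.97 (log2 fold change -2.08, SE 0.20, adjusted p = 6.83e-05). Nuggc (-2.33) and Neil1 (-2.36), expressed in germinal centre B cells, fell too. Camera called the list (adjusted p = 1.38e-05, and adjusted p = 0.341 with an estimated correlation). Under TMM scaling 9 genes fell and 1 rose. The sort left out cells positive for GL7 and FAS in both genotypes. Kappa reads (7.78% against 62.7% of light-chain constant reads) and Trac reads (2 against 15350) were lower in the knockout libraries as well.

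Proliferation genes fell most broadly. Of 41 tested, 32 fell, 9 were not called and 0 rose, and 35 fell when adjusted over the list alone. Mcm7, Mcm4 and Mcm3, parts of the replicative helicase, fell by 1.70, 2.08 and 2.17 on the log2 scale, and Ccna2, the S-phase and G2-phase cyclin A2, fell from 179 ± 45.5 to 30.1 ± 7.18 (log2 fold change -2.52, SE 0.25, adjusted p = 9.4e-05). Camera called the list (adjusted p = 1.67e-15; adjusted p = 0.341 with an estimated correlation). In the list of MYC and mTORC1 growth genes, 13 of 28 fell and 0 rose, with 16 lower when adjusted over the list alone and 6 lower under TMM scaling. Fbl, a nucleolar methyltransferase, fell from 265 ± 42.97 to 96.5 ± 9.01, and Ncl, which encodes nucleolin, fell from 1307 ± 233 to 746 ± 25.99; Pa2g4 (-1.36) and Ppan (-1.11) fell as well. Camera called this list (adjusted p = 4.54e-05; adjusted p = 0.611 with an estimated correlation).

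Cytosolic ribosomal protein genes moved the other way. Of 49 tested, 35 rose, 1 fell and 13 were not called; adjusted over the list alone, 37 rose and 1 fell, and under TMM scaling 45 rose and 0 fell. The mean log2 fold change of the list minus that of other genes was 0.70, and 0.18 under quantile normalization. Rpl19 rose from 3245 ± 265 to 5218 ± 172, Rplp1 from 4655 ± 631 to 8037 ± 558 and Rps14 from 4180 ± 399 to 6781 ± 476. The member that fell was Rps2 (log2 fold change -0.38), named after its values were seen. Camera called the list (adjusted p = 6.94e-31; adjusted p = 0.341 with an estimated correlation). Ribosomal protein genes have processed pseudogenes that can share their reads.

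More antigen presentation genes rose than fell. In the MHC class II list, 9 of 16 genes rose, 3 fell and 4 were not called, as they did adjusted over the list alone (camera adjusted p = 4.93e-07; adjusted p = 0.341 with an estimated correlation). H2-Aa and H2-Ab1, the alpha and beta chains of I-A, rose by 0.57 and 0.62 on the log2 scale. Cd74, the invariant chain, fell by 0.84, and Icosl, the ligand of ICOS on helper T cells, fell from 89.8 ± 23.6 to 16.6 ± 2.49. Among 11 age-associated B cell genes, 3 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.0173; adjusted p = 0.341 with an estimated correlation). Tbx21, the gene of T-bet, rose from 19.6 ± 14.2 to 129 ± 11.5 (log2 fold change 3.46, SE 0.88, adjusted p = 0.0172), Fcgr2b, an inhibitory Fc receptor, rose from 267 ± 62.4 to 561 ± 38.7, and Cxcr3 is shared with the memory list. Tbx21 was at 0 in heterozygous library 3, without which its log2 fold change was 2.28, and it was not called by DESeq2. Lgals1 fell by 1.33 on the log2 scale. The age-associated list was not called without heterozygous library 2.

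**Figure D3:**
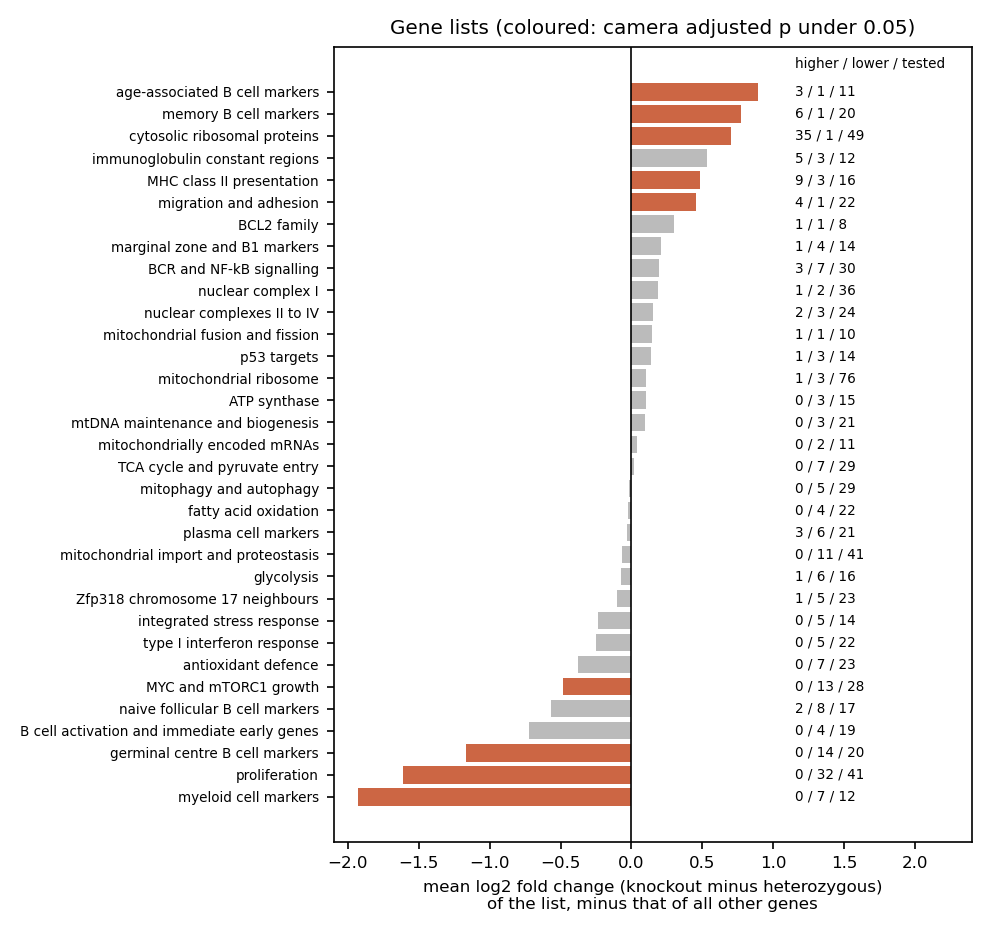
Mean log2 fold change (knockout minus heterozygous) of each of 33 gene lists minus that of all other genes, coloured where the camera adjusted p is under 0.05. Proliferation (0 higher, 32 lower of 41) and cytosolic ribosomal proteins (35 higher, 1 lower of 49) point in opposite directions.

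Of the 11 lists of mitochondrial genes, the subject of the series, camera called none in the main fit (authors' scaling, all libraries, mean of at least 10). It called 1 with no filter on low values and 1 under TMM scaling. Camera compares a list with other genes, whereas fry compares it with no change, and with the median gene at -0.25 fry called 4 lists, all lower: import (adjusted p = 0.0067), fatty acid oxidation (0.0067), TCA cycle (0.0148) and mitophagy (0.0372). Mitochondrial import and proteostasis had the most calls, 11 of 41 lower and 0 higher (14 lower adjusted over the list alone; camera adjusted p = 0.128), with 4 lower under TMM scaling. Tomm40, the pore of the outer membrane, fell from 234 ± 51.2 to 89.6 ± 11.95 (log2 fold change -1.36, SE 0.19, adjusted p = 0.000641), and Hspa9, the matrix chaperone mortalin, fell from 208 ± 34.03 to 97.4 ± 6.24. Immt (-1.16) and Samm50 (-0.90), which shape the cristae and the outer membrane, also fell, and all 4 kept their call under TMM scaling. In the TCA cycle list 7 of 29 genes fell, as adjusted over the list alone, among them Mdh2 (-0.48), Idh2 (-0.84) and Ogdh (-0.82), enzymes of the cycle; under TMM scaling 3 genes rose and 0 fell (camera adjusted p = 0.593 and 0.795). Of the transcripts encoded in mitochondrial DNA, 11 were tested: mt-Nd6 (-1.20) and mt-Cytb (-0.65) fell and 9 were not called, with 3 lower adjusted over the list alone and 0 called under TMM scaling (camera adjusted p = 0.593). Without heterozygous library 1 camera called this list (adjusted p = 0.0148; mean minus that of other genes -0.21, against 0.04 with all libraries) and the import list (adjusted p = 0.0381). With all libraries these had an adjusted p = 0.917 and an adjusted p = 0.701 with an estimated correlation. Among those not called, mt-Nd5 stood at a log2 fold change of -0.52 and mt-Nd3 at 9.87 ± 5.08 in the heterozygous and 21.7 ± 6.00 in the knockout libraries.

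Nuclear genes of the respiratory chain went both ways. In complex I, 1 of 36 genes rose and 2 fell, and 0 when adjusted over the list alone (camera adjusted p = 0.616); under TMM scaling 5 rose and 0 fell, and camera called the list (adjusted p = 0.014; adjusted p = 0.917 with an estimated correlation and the authors' scaling). Ndufa6 (0.48) rose under both scalings, Ndufa5 (-0.79) fell with the authors' scaling alone, and Ndufa3 (0.36) was called under TMM scaling alone. In complexes II to IV, Cox8a (0.38) and Uqcrh (0.48) rose and 3 of 24 genes fell, among them Cox7a2l (-0.61) and Sdhc (-0.65); under TMM scaling 3 rose and 0 fell (camera adjusted p = 0.988 and 0.0836). In ATP synthase 3 of 15 genes fell, Atp5b (-0.47), Atp5g3 (-0.51) and Atpif1 (-0.68), and under TMM scaling 1 rose and 0 fell (camera adjusted p = 0.593 and 0.388). Counts adjusted over the list alone were the same for these last lists. Of 76 mitochondrial ribosome genes, Mrps16 (0.50) rose and 3 fell, Mrps18a (-1.23), Mrpl18 (-0.60) and Mrps28 (-0.93); adjusted over the list alone 1 fell, and under TMM scaling 4 rose and 1 fell (camera adjusted p = 0.988 and 0.286).

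Of the other mitochondria lists, fatty acid oxidation had 4 of 22 genes lower (Acadl, -0.87; Etfa, -0.79; Acsl5, -0.88; Acads, -1.63; camera adjusted p = 0.593). Mitophagy and autophagy had 5 of 29 lower (Phb2, -0.74; Atg13, -1.47; Atg3, -0.63; Optn, -1.51; camera adjusted p = 0.864). Mitochondrial DNA maintenance and biogenesis had 3 of 21 lower (Pprc1, -1.36; Nrf1, -1.19; Tfb1m, -1.46; camera adjusted p = 0.74), with a median of 0.13 and a mean of -0.21. In each 0 genes rose, and counts adjusted over the list alone were the same; under TMM scaling the higher and lower genes numbered 0 and 1, 2 and 0, and 1 and 1, and the named mitophagy genes stayed negative but lost their calls. In fusion and fission, Fis1 (0.41), a fission factor, rose and Mfn2 (-1.37), a fusion GTPase, fell among 10 tested genes (camera adjusted p = 0.593); Mfn2 was not called under TMM scaling (adjusted p = 0.105).

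The lists of this paragraph were not called by camera in the main fit, with the authors' scaling, all libraries and a mean of at least 10. Glycolysis had 6 of 16 genes lower and 1 higher (Pkm, -0.84; Hk1, -2.59; camera adjusted p = 0.194), antioxidant defence 7 of 23 lower (Keap1, -1.70; adjusted p = 0.29) and the integrated stress response 5 of 14 lower (Shmt2, -1.02; adjusted p = 0.194). In the BCL2 family Mcl1 (-1.50), a survival factor, fell and Bcl2a1d (1.08) rose among 8 tested (adjusted p = 0.41), and among p53 targets Btg2 (1.24) rose and 3 of 14 fell, with Ei24 at -2.25 (adjusted p = 0.593). In the type I interferon list 5 of 22 fell, with Isg20 at -1.08 and Irf7 at -1.76 (adjusted p = 0.593). B cell receptor and NF-kB signalling had 3 of 30 higher and 7 lower (Dok3, -0.95; adjusted p = 0.324), but 9 higher and 2 lower under TMM scaling, where camera called it (adjusted p = 0.0394; adjusted p = 0.873 with an estimated correlation and the authors' scaling). Immediate early genes had 4 of 19 lower (Zfp36, -1.91; Dusp2, -1.67; adjusted p = 0.0573), and under TMM scaling camera called the list (adjusted p = 0.0191; adjusted p = 0.701 with an estimated correlation and the authors' scaling). Naive follicular genes, which include Zfp318 and Ighd, had 8 of 17 lower and 2 higher (adjusted p = 0.29). Marginal zone and B1 genes had 4 of 14 lower and 1 higher (Myof, -1.75; Dtx1, -1.06; adjusted p = 0.719). Plasma cell genes had 6 of 21 lower and 3 higher (Irf4, -1.91; adjusted p = 0.943), and immunoglobulin constant regions 3 of 12 lower and 5 higher (adjusted p = 0.0603). Neighbours of Zfp318 on chromosome 17 had 5 of 23 lower and 1 higher, with Hsp90ab1 at -0.84 and Polh at -2.16 (camera adjusted p = 0.41). Fry, which compares a list with no change, called these neighbours (adjusted p = 4.13e-05). Their median log2 fold change was -0.46, and that of all genes was -0.25. Fry also called others of these lists, such as naive follicular genes (adjusted p = 0.00167).

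TMM scaling moved the balance of several of these lists. Its higher and lower genes numbered 1 and 2 in glycolysis, 3 and 2 in antioxidant defence, 0 and 1 in the integrated stress response, 1 and 1 in the BCL2 family, 2 and 1 among p53 targets and 1 and 3 in the interferon list. They numbered 6 and 3 among plasma cell genes, 5 and 5 among naive follicular genes, 3 and 2 among marginal zone and B1 genes, 1 and 4 among immediate early genes, 6 and 3 among immunoglobulin constant regions and 1 and 3 among neighbours of Zfp318. Of 25 alternatives with the preset correlation, camera called the immediate early genes in 14, immunoglobulin constant regions in 6, B cell receptor and NF-kB signalling in 5 and naive follicular genes in 3, among them edgeR (adjusted p = 0.0337) and DESeq2 (adjusted p = 0.0114). Naive follicular genes and immunoglobulin constant regions each had an adjusted p = 0.701 with an estimated correlation and the authors' scaling. Glycolysis, antioxidant defence and the integrated stress response were each called in 1, and the other lists of the preceding paragraph in 0. With an estimated correlation and the authors' scaling these 3 had a camera adjusted p = 0.641, 0.701 and 0.701.

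Some transcripts of T cells and macrophages were higher in the heterozygous libraries. Trac, the constant region of the T cell receptor alpha chain, stood between 178 and 667 in each heterozygous library, from 15350 reads, and had 2 reads over the knockout libraries (log2 fold change -8.43, adjusted p = 1.25e-06). Of 4 tested T cell genes 3 fell and Cd2, which B cells also express, rose (0.74). In the myeloid list 7 of 12 genes fell and 0 rose; adjusted over the list alone, 7 fell and 1 rose (camera adjusted p = 0.0325; adjusted p = 0.701 with an estimated correlation). Hmox1, a haem-degrading enzyme of red pulp macrophages, fell from 175 ± 98.5 to 4.32 ± 2.99, C1qc from 80.4 ± 54.4 to 5.13 ± 1.92, Vcam1 from 64.2 ± 34.6 to 2.73 ± 2.97 and Slc40a1, the iron exporter ferroportin, from 39.9 ± 24.2 to 0.816 ± 1.28. The call on the myeloid list was lost without heterozygous library 1, 3 or 4, without both 1 and 3, with a pseudocount of 0.25 and with no filter on low values; at a minimum mean of 50 too few members were left for a test. Lists of other cell types had too few tested genes for camera. Nkg7, of natural killer cells, stood at 46.7 ± 91.4 in the heterozygous and 0.873 ± 0.714 in the knockout libraries, Hba-a1 and Hbb-bt, of red cells, at 30.8 ± 28.4 and 19.3 ± 7.67 against 3.50 ± 0.922 and 8.58 ± 2.11, and Flt3 and Bst2, of dendritic cells, at 37.5 ± 18.05 and 95.1 ± 37.5 against 63.7 ± 8.72 and 53.3 ± 11.5; none of these passed, but Flt3 was called higher under TMM scaling (adjusted p = 0.0253). Of the stromal list, Cr2, which B cells also express, fell by 0.59 on the log2 scale, and Pecam1 (0.49) did not pass; under TMM scaling Cr2 was not called (adjusted p = 0.248) and Pecam1 was called higher (adjusted p = 0.00446).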

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

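The test with equal read numbers and the test of other splits of the libraries were written before the results were seen; all other tests given here were chosen only after the result was seen.

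A total of 256 groups of 4 values were tested for a single library far from the other 3 (its gap to the nearest of them over the whole range, above the 95% critical value of Dixon; this ratio is given first in each case), and 13 were found where chance alone gives 12.8, or about 1 in 20, so their number is what chance gives. Ighm was high in heterozygous library 1 (0.938; 19827 against 11750 to 12251). Trac had its only knockout reads in library 3 (1.0; 0.299 against 0). Gnas (0.876) was high in knockout library 2, H2-Aa (0.843) in knockout library 3 and Ndufa3 (0.868) in knockout library 4. Sdhc was low in knockout library 2 (0.880), and S1pr2 was low in heterozygous library 4 (0.878; 51.7 against 117 to 126). Irf4 (0.833) was high in heterozygous library 2 and Cd2 (0.843) in heterozygous library 3. Nkg7 was found almost only in heterozygous library 3 (0.983; 184). The switched share was low in heterozygous library 2 (0.905; 3.60%). In heterozygous library 1 the V segments Ighv11-2 (0.946; 41.4% of heavy-chain V reads) and Igkv14-126 (0.846; 42.5% of kappa V reads) were high together.

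The knockout libraries resembled one another (r from 0.974 to 0.978) and the heterozygous libraries did not (0.777 to 0.807, no closer than the 0.795 to 0.832 between genotypes), with a median SD 2.67 times as large. Sequencing depth does not account for it: with every library thinned to 7995676 reads the ratio was 2.66. Sequencing of 1 cDNA pool as 4 knockout libraries was tested on kappa V segments. Among the knockout libraries these varied 2.28 times as much as other genes of their level (interval 1.65 to 3.49, 26 segments). The ratio was 2.60 among the heterozygous libraries, where genes in general varied more. The knockout ratio speaks against a single pool of cDNA but leaves open cells taken from a shared pool. The most abundant kappa V segment was Igkv1-135 in every knockout library and in heterozygous library 4. It differed between heterozygous libraries 1, 2 and 3 (Igkv14-126, Igkv6-15 and Igkv6-23). Cells from a shared pool could give the recurrence in the knockout, but this was not tested. Fewer RNA molecules behind the heterozygous libraries were tested by the fall of the CV with level, at a slope of -0.372 there and -0.375 in the knockout. The slope cannot decide this, since fewer molecules can raise the CV without steepening its fall. Of 8221 genes with a mean of at least 10 in the heterozygous libraries, 384 were at 0 in at least 1 of them. In the knockout libraries 0 of 7438 such genes were. Fewer molecules or more varied cells could each give such zeros, so the explanation is left open. A biological explanation, more varied cells in the heterozygous libraries, was not separately tested.

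Kappa chains and many heavy-chain V segments marked the heterozygous libraries, although the sort was for NP binding, which B1-8hi gives with lambda-1. Extra immunoglobulin RNA from a few secreting cells would leave Iglc1 alike in both groups, but Iglc1 was 4.63 to 8.69 times as high in the knockout over the 16 pairs of libraries, so such RNA is not the only difference. Whether it adds to the kappa and Ighm reads is left open: Jchain (220 against 8.04), Irf4 (42.8 against 10.7), Prdm1 (14.1 against 0.784) and Sdc1 (11.3 against 0.252), which go with secreting cells, had the higher mean in the heterozygous libraries, the last 2 chosen after their values were seen. Against it, Prdm1 and Sdc1 were at 0 in heterozygous library 4 (exact permutation p = 0.143 each). Jchain was lowest (120) in library 1, where Ighm and Igkc were highest, but Prdm1 (23.8) and Sdc1 (26.8) were highest there too. The plasma cell list had 3 genes higher and 6 lower, or 6 higher and 3 lower under TMM scaling. Reads counted for the wrong near-identical V segment would stay in the family of Ighv1-72, but 38.4% to 67.5% of heavy-chain V reads lay outside that family in the heterozygous libraries; whether genotype or the sort brought the difference about was not tested.

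T cell receptor and macrophage transcripts were seen in the heterozygous libraries. T cells among the sorted cells of heterozygous library 3 fit the values, since Cd3d, Cd3e and Cd3g, chosen after their values were seen, together reached 14.4% of Trac there. In heterozygous libraries 1, 2 and 4 they reached 1.53% at most, which by itself speaks against intact T cells, but Trbc2, also chosen after its values were seen, stood at 35.3, 27.1 and 28.5 there beside Trac at 568, 268 and 178, against 69.3 beside 667 in library 3, so the source of Trac is left open. The source of the macrophage transcripts was not tested; Adgre1 (15.7 against 50.6) and Tyrobp (117 against 131), also chosen after their values were seen, had no higher mean in the heterozygous libraries. The gate on B220 and NP binding is meant to remove whole T cells and macrophages, but whether it did was not tested. No biological explanation was tested.

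Of the 35 ways to split the 8 libraries into groups of 4, 1 gave as many calls as the real one, which was the real split itself (1575 calls). The highest other split gave 0. With the knockout libraries so alike, other splits had little prospect of calls. The test cannot tell whether genotype, the sort or a shared pool of cells sets the groups apart.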

How the results depend on the processing

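Zfp318 and Ighd kept direction and call under every alternative (Ighd from -5.66 to -5.23). Of 3222 comparisons of 129 named genes and lists with an alternative, 2799 were the same, 364 lost and 55 gained a call and 4 turned direction. Only 24 of the 129 were the same under every alternative. With the knockout libraries as 1 sample 84 lost their call, and under TMM scaling 27 did. Genes called higher numbered 432 without a filter, where more genes were tested. Higher and lower genes numbered 613 and 616 under TMM scaling, 597 and 665 under quantile normalization and 486 and 727 with edgeR; DESeq2 gave 646 higher. For TMM the shift of the median by 0.33 moves calls from lower to higher by construction. The median log2 fold change also moved up under quantile normalization (0.35), edgeR (0.20), DESeq2 (0.20) and the length and GC correction given next (0.24). Whether these shifts alone account for the counts was not tested, nor was the cause of the count without a filter. Among alternatives chosen after seeing the data, the knockout libraries as 1 sample gave 4 and 42, lost by construction with fewer samples and only the heterozygous spread; correction for length and GC gave 478 and 714, and leaving out both heterozygous libraries 1 and 3 gave 489 higher and 1875 lower, where the cause was not tested. Leaving out each library in turn gave 168 to 366 higher and 801 to 1516 lower. The estimated correlation called 0 lists and fry 21. Of mitochondria lists, 1 was called without a filter, under TMM, quantile, edgeR and DESeq2, and with both heterozygous libraries 1 and 3 left out. Fry called 4, and leaving out single libraries 0 to 2 (import and mitochondrially encoded, without heterozygous library 1). The list called was not always the same. Of 25 alternatives with the preset correlation, camera called complex I in 4, import in 3 and mitochondrially encoded mRNAs in 1. Under TMM the list was complex I, with 5 genes higher and 0 lower. Atp5d turned to 0.0112 under TMM, Mff to 0.0170 under TMM and 0.0992 under quantile normalization, and Nkg7 to 0.141 without heterozygous library 3, against -2.37 without library 1; none of these was called. The cause was not tested. Libraries share only a number between genotypes (correlation -0.034 to 0.0366), and a block on it gave 250 higher and 1095 lower. At these depths, but with equal spread in both genotypes unlike the data, simulation recovered 34.4% of 2-fold changes.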

Other observations

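Of the tests given here, that of the region around Zfp318 was written before the results were seen; the others were chosen only after the result was seen.

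Heterozygous library 1 held most reads of Ighv11-2 and Igkv14-126, chosen after their values were seen, at 1198 and 6337 against at most 59.5 and 395 in the other heterozygous libraries, and 0 and at most 31.0 in the knockout libraries. Sf3a2, a splicing factor subunit needed in all cells, fell in every alternative, from -4.52 to -3.68 on the log2 scale. Among macrophage genes chosen after their values were seen, C1qa stood at 57.7 against 4.27 and C1qb at 132 against 7.29.

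A first hypothesis was that fewer unswitched or kappa-expressing cells lowered Ighd. In all 16 pairs of libraries Ighd fell further than Ighm or Igkc, by a difference of -1.75 to -4.60 on the log2 scale. This speaks against an even loss of unswitched or kappa-expressing cells as the only cause. A loss of mainly those cells richest in Ighd would also lower Ighd further than Ighm or Igkc, so the test cannot decide on it. Igkc was chosen after its values were seen.

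A further hypothesis was that strain DNA or a position effect around the targeted allele changes genes near Zfp318. Within 2 Mb, 10 of 37 tested genes were called (27.0%; 9 lower, 1 higher), against 20.0% elsewhere (one-sided Fisher exact p = 0.192). The test could not tell.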
